A study of Homo sapiens with 24 samples.

How the data were processed

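Formaldehyde-assisted isolation of regulatory elements followed by sequencing (FAIRE-seq) enriches DNA that is poorly crosslinked to nucleosomes, and so marks open chromatin. It was applied to MonoMac 6, an established human monocytic cell line, as wild type (WT) and with a knockout (KO) of 5-lipoxygenase, the enzyme encoded by ALOX5 that starts leukotriene synthesis. Per the labels, cells were differentiated for 72 h with 1 ng/mL TGF-β1 and 50 nM calcitriol, the active form of vitamin D. They were given 1 µg/mL lipopolysaccharide (LPS) or none, here called unstimulated. The summit lists of the unstimulated groups carry PBS in their names, which can be read as a vehicle control. The labels disagree on the length of the LPS treatment: the protocol text gives 2 h and the sample characteristics give 6 h. There were 24 samples, 12 from FAIRE and 12 inputs, with 3 of each kind in each of 4 groups. Input samples entered no comparison.

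Alignment and peak calling are listed in the submitters' processing notes as Bowtie2, MACS2 and the genome builds GRCh38 and hg38, without versions, and the peak names carry a mark of duplicate handling. Each of the 4 deposited files was a list of summits, each 1 base wide, and each belonged to a whole group and not to a sample, per the labels. Whether the 3 samples of a group were pooled before calling is not given in the sources used here, because the peak names of all 4 lists carry the same tag, N3, which can be read as the number of samples or as a replicate number, and a single alignment name each. Use of the inputs as control and the read depth are not given either. The deposited score of a summit was a −log10 p-value or q-value (which of them is not given in the sources used here), as the authors' peak caller wrote it. It started at 1 in every list, which corresponds to a threshold of 0.1. Scores were used only to rank or filter summits within a list.

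Peak widths were absent from the summit lists, although the design fixed before the data were examined had assumed them. Each summit was therefore widened to a window of 251 bases, and summits of different lists were shared when their windows overlapped by at least 1 base, that is, within 250 bases. The gene table used here (RefSeq, GRCh38, the build of the lists) held gene starts and ends without strand, so the planned promoter was replaced by 1000 bases on either side of either annotated gene end. This counts summits at 3′ ends together with those at promoters. Exons, untranslated regions and introns could not be separated, and the 11 planned sequence motifs were not searched, because no genome sequence was used here. Summits on chromosomes 1 to 22 and X were kept. The table gave 19974 protein-coding genes, and 38151 with long non-coding RNA genes added for the location of summits. Of the 464 entries in the gene lists, 461 matched a gene in the table.

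The length of a summit list depends on depth and on the noise of the library, so each comparison was also made with the 102417 highest-ranked summits of every list, the length of the shortest list ("equal numbers"). Chance overlap was the mean of 5 random draws of positions spread evenly along each chromosome. Summits of all 4 lists at most 250 bases apart were joined into union regions, and each region was classed by the lists that held a summit in it. Regions in both WT lists and no KO list, or the converse, differed by genotype in both stimulation states, and regions in both LPS lists or both unstimulated lists differed by stimulation in both genotypes. The remaining pairs, WT unstimulated with KO LPS and WT LPS with KO unstimulated, follow neither factor alone and served as the gauge of noise. A genotype difference whose direction turns between the stimulation states would also fall in them, so they may hold more than noise. The geometric mean of a pair of opposite patterns was divided by that of the crossed pair, to reduce the effect of list length. Shares of summits carry Wilson 95% intervals, ratios of shares a 95% normal interval on the log scale, and gene-list ratios an exact binomial 95% interval; all intervals cover counting error only.

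For 16 gene lists fixed before the data were examined, summits within 50000 bases of either gene end were counted. The log2 ratio of these counts between the lists of a comparison was centred on the median of 10000 random gene lists of the same size, matched on deciles of the mean summit number. A summit near several members of a list was counted for each of them. The binomial intervals treat these counts as independent and are too narrow where members lie close together. The random lists were not matched on such clustering. The percentile among the random lists describes these 4 summit lists and is no p-value. Chromosomes and 5-Mb bins with at least 20 summits were compared as shares of each list. Genes named in the text followed a rule fixed beforehand: ALOX5; up to 2 members per gene list and direction with a summit at a gene end in 1 list of a comparison only, both as deposited and with equal numbers; the 5 best-ranked protein-coding genes per comparison and direction; the 5 best-ranked genes per genotype-only or stimulation-only pattern; and up to 3 members per gene list present in all 4 lists. Genes named outside the rule are said to be so.

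With 1 list per group there was no replicate spread, so no test was made and no p-value is given. Alternatives were a score of at least 5, all sequences, reciprocal overlap of 50%, the better-ranked 50% of each list, union regions joined up to 500 bases, gene ends of 500 or 2500 bases and a gene window of 10000 bases. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated lists of equal length, with positions drawn evenly along the chromosomes and gene-list members drawn at random. Unequal list lengths, uneven summit density and clustered list members were therefore not covered. For KO against WT unstimulated, all 200 genes planted with a one-sided summit among 19974 were found, and a planted shared percentage of 52.2% was measured as 52.7% over 67000 summits. For presence patterns over 142137 simulated regions, a planted genotype ratio of 2 was measured as 1.99 and a planted stimulation ratio of 1.25 as 1.25. For LPS against unstimulated in WT, 6% of 200 unchanged gene lists of 30 genes fell outside the middle 95% of random lists, and 19 of 20 lists planted with a log2 ratio of 0.58 lay above it, with a mean of 0.59.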

Results

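Open chromatin was mapped by FAIRE-seq in differentiated MonoMac 6 cells to compare 5-lipoxygenase knockout with wild type cells, each unstimulated and after LPS, the bacterial cell wall component sensed by TLR4. Each of the 4 groups, of 3 FAIRE samples by the labels, was represented by 1 list of summits, which may have been called on pooled samples or on a single one. The WT unstimulated list held 184238 summits, the WT LPS list 102417, the KO unstimulated list 142486 and the KO LPS list 128045. Their median scores were 2.81, 2.63, 2.93 and 2.71 on the authors' −log10 scale. Read depth is unknown and no replicate values were analysed here, so no difference below could be set against a spread between replicates.

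ALOX5 (gene ID 240; chromosome 10, 45374216 to 45446117, GRCh38), the gene targeted in the knockout, had no summit within 1000 bases of either end in any list. Summits lay within the gene in all 4 lists, KO included. Union regions shared by all 4 lists were found at 45376455 to 45376555, 45380266 to 45380428, 45404220 to 45404316 and 45437530 to 45437612. The first of these, 2239 to 2339 bases from the lower-coordinate end of the gene, was the highest-scoring ALOX5 summit in both unstimulated lists, with scores of 11.3 in WT and 18.1 in KO. In both LPS lists the region at 45404220 to 45404316 scored highest, with 9.23 in WT and 10.5 in KO. Scores cannot be compared between lists, and a summit list does not show whether the coding sequence is disrupted, so these values do not check the genotype labels.

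**Figure D1:**
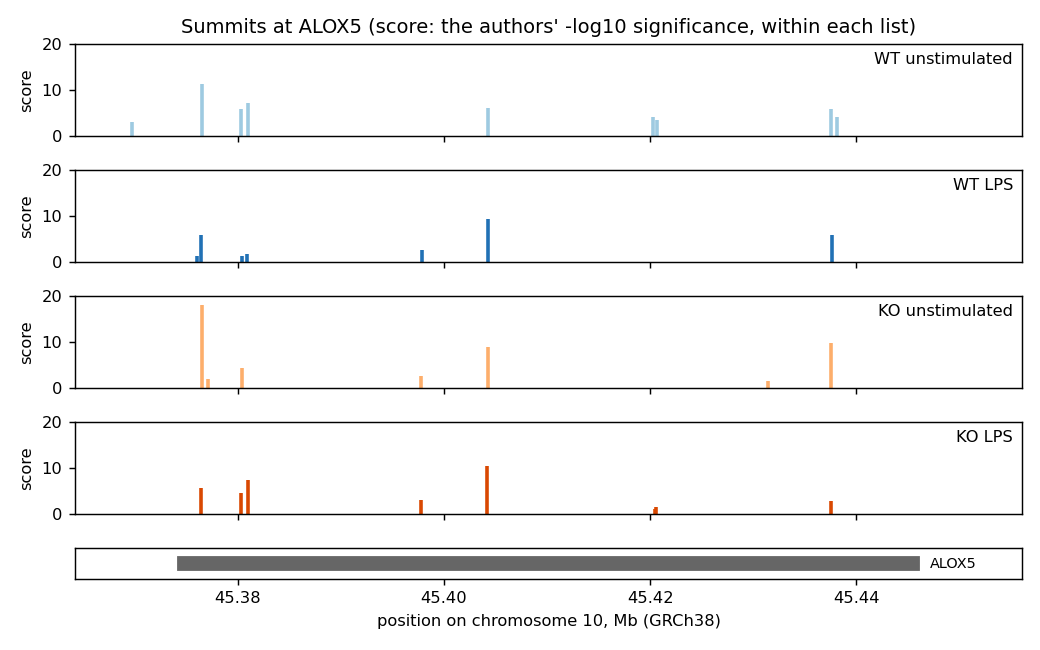
Summits in and within 10000 bases of ALOX5 in each of the 4 lists, with position on chromosome 10 in Mb on the x axis and the authors' −log10 score on the y axis; the grey bar is the annotated gene. Regions such as 45404220 to 45404316 carry a summit in all 4 lists, and no summit lies within 1000 bases of either gene end.

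The first comparison asked how chromatin differed between KO and WT cells without LPS. Of protein-coding genes, 1051 had a summit at a gene end in KO only and 1846 in WT only, while 5257 had one in both; with equal numbers 1309 were in KO only and 1424 in WT only. Genes of the LPS early response list with a summit in KO only included NFKBIA, the inhibitor of NF-κB, with a score of 8.24, and SOD2, a mitochondrial superoxide dismutase, with 3.98. Those in WT only included MAFF with 3.15 and IL6, a cytokine gene in a 5-Mb bin with fewer KO summits (log2 −1.37), with 5.65. The list's nearby summits had a centred log2 ratio of 0.23 in KO (95% counting interval 0.04 to 0.41; percentile 99.7 of random lists), which with equal numbers was 0.14 and inside the middle 95% of random lists. Of 28 chromatin and RNA processing genes, 16 had a summit in WT and 9 in KO, with 7 in WT only, among them DNMT1 and EP300, and 0 in KO only; their nearby summits had a log2 ratio of −0.15, and −0.42 with a window of 10000 bases (percentile 0.61). Of 25 vitamin D targets, 4 had a summit in WT only, among them CD93 and CYP24A1, the calcitriol-degrading enzyme, and 0 in KO only. Both genes lie on chromosome 20, in bins with log2 ratios of −0.38 and −0.27. The nearby summits of the vitamin D list went the other way, with a centred log2 ratio of 0.21 in KO (−0.05 to 0.48; percentile 97.4), 0.38 with a window of 10000 bases (percentile 98.9) and 0.03 with equal numbers. The highest-ranked genes in WT only were SESN3 (score 30.1), ZNF577, HLA-DPB1, SHANK1 and ZNF417, and in KO only RGSL1 (22.8), RAP2A, MTMR10, TMEM43 and CDK2. Over all summits, 57.2% of KO summits were shared with WT and 44.7% of WT summits with KO. Against evenly placed positions the shares were 3.68% and 2.89%, which leaves out the uneven density of summits. With equal numbers the shares between the lists were 48.7% and 48.9%. Among the top 5000 summits of each list, 99.1% and 98.6% were shared, so that one-sided summits were mostly low-ranked.

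After LPS, 2099 genes had a summit at a gene end in KO only and 847 in WT only, with 4864 in both. The KO list was the longer of the pair, and with equal numbers 1827 genes were in KO only and 1028 in WT only. Of 29 focal adhesion and integrin genes, 7 had a summit in WT and 13 in KO; the 6 in KO only included PTK2B, a kinase of the focal adhesion kinase family, with a score of 6.30, and ZYX, and 0 were in WT only. Their nearby summits had a log2 ratio of −0.04. Interferon response genes held more nearby summits in KO, with a centred log2 ratio of 0.44 (0.15 to 0.73, percentile 99.9). With a window of 10000 bases it lay inside the middle 95% of random lists (percentile 96.5). The member IFI44L lies in a 5-Mb bin with more KO summits in both states. Without bins that differed in both states the ratio was 0.33 (percentile 98.6), and with each summit counted once 0.36. Of these genes, 5 of 28 had a gene-end summit in KO only, among them IFIT2 and RIGI, an RNA sensor, against 3 in WT only, among them MX2 and IFIT3. VEGF and angiogenesis genes held fewer nearby summits in KO, with a log2 ratio of −0.37 (−0.63 to −0.11; percentile 0.55), inside the middle 95% with equal numbers (percentile 3.67) and with a window of 10000 bases (percentile 14.0). The LPS early response list had a log2 ratio of −0.16 (−0.33 to 0.01), while 4 of its members, among them IRF1 and MAFF, had a gene-end summit in KO only and 2 in WT only, CCL4, a chemokine gene, and IL6, whose bin had a log2 ratio of −1.50. The best-ranked genes in KO only were FMC1-LUC7L2 (17.4), FXR2, the neighbours IFT20 and TNFAIP1, which share a summit, and SESN3, and in WT only MTMR10 (16.7), CDK2, FPR2, TNRC6C and RGSL1. Of KO summits 40.4% were shared with WT, and of WT summits 50.3% with KO; with equal numbers the shares were 44.1% and 45.1%.

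MTMR10, CDK2 and RGSL1 were in the WT LPS and KO unstimulated lists and absent from the other 2, and SESN3 was in WT unstimulated and KO LPS only, so that their direction turned between the stimulation states. Genes that differed by genotype in both states numbered 215 for WT only and 287 for KO only, beside 426 and 110 genes in the crossed patterns. The best-ranked in WT only were HLA-DPB1, an MHC class II gene (scores 17.7 and 10.4), FPR2, a formyl peptide receptor (11.6 without LPS; within 50000 bases 22 and 13 WT summits and 0 KO summits), GSDMC, ZNF555 and MDFIC. In KO only they were AKTIP (8.24 and 12.0), the neighbours BST2, an interferon-induced antiviral gene, and MVB12A, which share a summit (10.6 and 7.82), CDCA4 and WARS1. Over all union regions, 9281 were in both WT lists only and 9613 in both KO lists only, against 11351 and 5027 in the crossed patterns. The geometric mean of the genotype patterns was 1.25 times that of the crossed patterns, and 1.23 times with equal numbers; 2132 of the WT-only and 1221 of the KO-only regions lay in 76 bins of 5 Mb whose KO and WT shares differed in both states.

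**Figure D2:**
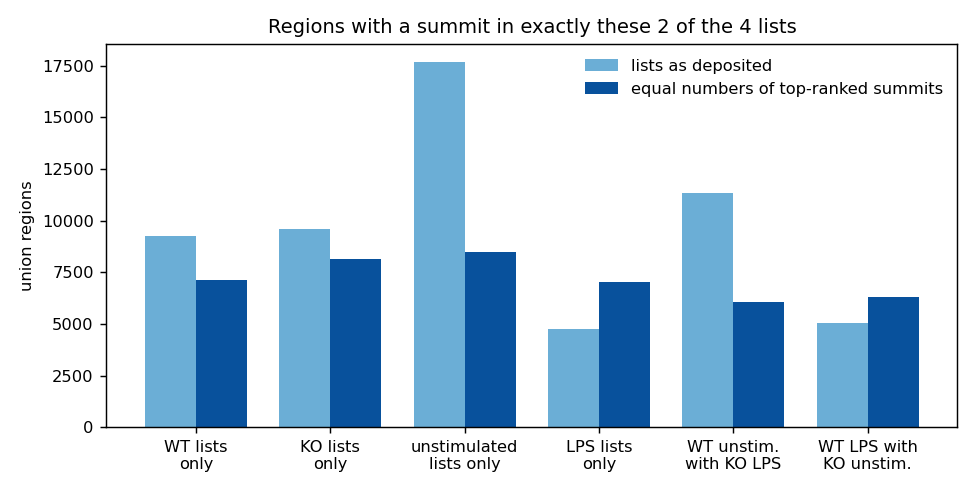
Number of union regions (y axis) with a summit in exactly the pair of lists named on the x axis, for the lists as deposited and for equal numbers of top-ranked summits. The crossed pairs at the right, which follow neither genotype nor stimulation alone, hold 11351 and 5027 regions as deposited, and the genotype pairs 9281 and 9613.

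The KO and WT lists also differed over long stretches of chromosomes, in the same direction in both stimulation states. The first 55 Mb of chromosome 7, which holds IL6 and ACTB, a housekeeping gene, had a KO share of summits 0.341 times that of WT without LPS (0.318 to 0.365) and 0.289 times after LPS (0.267 to 0.312). Chromosome 2 had ratios of 0.661 (0.645 to 0.678) and 0.656 (0.637 to 0.676), and chromosome 20 had 0.731 and 0.710. Higher shares in KO were found at 45 to 110 Mb of chromosome 1, with ratios of 1.75 (1.68 to 1.82) and 1.89 (1.80 to 1.99), and at 160 to 170 Mb of chromosome 6, with 2.74 and 2.64. ALOX5AP, which encodes the 5-lipoxygenase-activating protein and had a gene-end summit in all 4 lists, lay in a bin with log2 ratios of −0.59 and −0.60. At 51658661 to 51838691 of chromosome 19, a stretch singled out after its values were seen, 59 WT summits (32 unstimulated and 27 LPS) and 0 KO summits were listed. It holds FPR1, FPR2, FPR3, HAS1, SPACA6 and ZNF577.

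**Figure D3:**
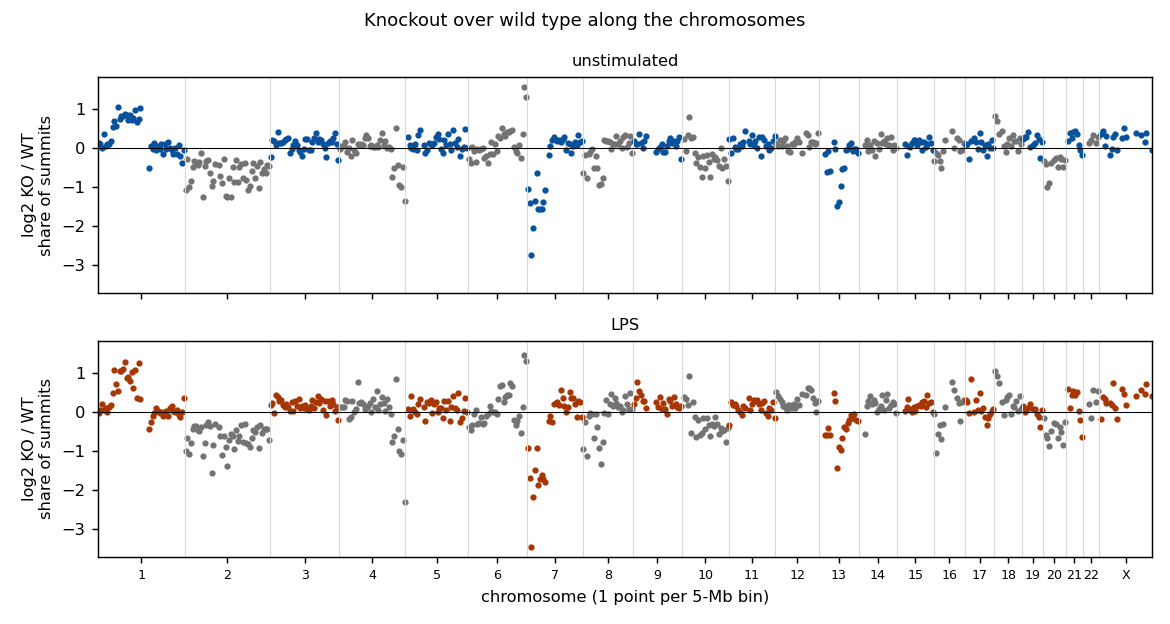
Log2 ratio of the KO to the WT share of summits (y axis) in 5-Mb bins along the chromosomes (x axis), without LPS above and after LPS below; colours alternate by chromosome. The same segments stand apart in both panels, such as the first 55 Mb of chromosome 7, with share ratios of 0.341 and 0.289.

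In WT cells, LPS against no stimulation asked which chromatin opened or closed on TLR4 stimulation. Summits near LPS early response genes, a list of NF-κB targets, cytokines and chemokines, made up a larger part of the LPS list, with a centred log2 ratio of 0.81 (0.63 to 0.98; percentile 100), and 33 of 40 members lay above the median of random lists. Summits within 50000 bases went from 4 to 12 at NFKBIA and from 19 to 28 at SOD2, although the whole list was 0.556 times as long. Of the 40 members, 6 had a gene-end summit after LPS only, among them TNF, which encodes the inflammatory cytokine (score 10.8), and REL, an NF-κB subunit (7.61), and 3 without LPS only, among them IRF1 and TNFAIP2. Of 32 monocyte and macrophage markers, 18 had a gene-end summit without LPS and 11 after, with 7 in the unstimulated list only, among them S100A8 and CEBPB, and 0 in the LPS list only; the log2 ratio of their nearby summits was 0.01, and −0.28 with equal numbers. VEGF and angiogenesis genes had a log2 ratio of 0.43 (0.18 to 0.68; percentile 99.9), which was 0.27 without FLT1, 0.28 with equal numbers and inside the middle 95% with a window of 10000 bases (percentile 94.4), and housekeeping genes 0.36 (0.03 to 0.68; percentile 99.8), which with equal numbers was 0.18 and inside the middle 95% of random lists. Of all protein-coding genes, 833 had a gene-end summit after LPS only and 2225 without LPS only; with equal numbers these counts were 1394 and 1401. Of the LPS summits 61.8% were shared with the unstimulated list, and 34.6% of the unstimulated ones with the LPS list.

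In KO cells the LPS early response genes also held more summits after LPS, with a centred log2 ratio of 0.42 (0.24 to 0.60, percentile 100). Of their 40 members, 36 lay above the median of random lists. With a window of 10000 bases the ratio was 0.39, below leukotriene and prostanoid pathway genes (0.43) and chromatin and RNA processing genes (0.60). The counts near NFKBIA were 6 without and 13 with LPS, and near CCL4 5 and 17. Gene-end summits were found after LPS only at 4 members, among them TNF (4.57) and NFKB2 (6.55), and without LPS only at 1, SOD2. Of 28 chromatin and RNA processing genes, 9 had a gene-end summit without LPS and 16 with it, with 7 in the LPS list only, among them EZH2, a histone methyltransferase (12.1), and DOT1L, and 0 in the unstimulated list only. Their log2 ratio of nearby summits was 0.27 (0.00 to 0.53; percentile 99.7), and 0.60 with a window of 10000 bases. For leukotriene and prostanoid pathway genes it was 0.29 (0.05 to 0.54; percentile 99.8), although 10 of 33 members had a gene-end summit without LPS and 10 with it. After LPS only were 2 of them, PTGER2, a prostaglandin receptor (4.88), and COTL1, and without LPS only 2, the neighbouring leukotriene B4 receptor genes LTB4R and LTB4R2, which share 1 summit (2.28). Of all protein-coding genes, 1710 had one after LPS only and 1055 without LPS only; with equal numbers these counts were 1844 and 937. Of LPS summits 51.9% were shared with the unstimulated list, and 46.3% the other way.

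Stimulation differences seen in both genotypes comprised 4756 regions in both LPS lists only and 17666 in both unstimulated lists only, with a geometric mean 1.21 times that of the crossed patterns (1.25 times with equal numbers). With equal numbers these were 7030 and 8475 regions, so that most of the excess of unstimulated-only regions was lost. At gene ends 210 genes were LPS-only and 282 unstimulated-only, and with equal numbers the direction turned, to 344 and 179. The geometric mean of these gene counts was only 1.12 times that of the crossed genes, and 1.16 times with equal numbers. LPS only were RHOT1, a mitochondrial GTPase (scores 15.6 in WT and 15.4 in KO), TSPAN10, FOXA3, BAIAP2 and CD22, and among the list members TNF, DUSP2, IFI44L, RIPK1, TBK1, TGIF1, CREBBP and HSP90AB1. Unstimulated only were OXSR1 (33.4 and 25.1), ACTRT3, IDH3B and the neighbours MADD and NR1H3, which share a summit, and among the list members S100A8, ITGAX and CSF2RB, all myeloid markers, with CHUK, MS4A1 and FAP. DUSP2, ITGAX, CSF2RB and FLT1 lie outside the naming rule and were named after their values were seen. IFI44L and TGIF1 lay in bins with more KO summits, with log2 ratios after LPS of 1.28 and 1.04. Of the 40 LPS early response genes, 29 lay above the random median after LPS in both genotypes and 0 below it in both. For housekeeping genes the same counts were 14 and 5 of 30, and for monocyte markers 11 and 8 of 32. Of all 64 gene-list ratios, 9 lay outside the middle 95% of random lists, where 3.2 are expected by chance. The comparisons share lists, so that the WT LPS list enters both the VEGF value against KO and the VEGF value against unstimulated cells.

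**Figure D4:**
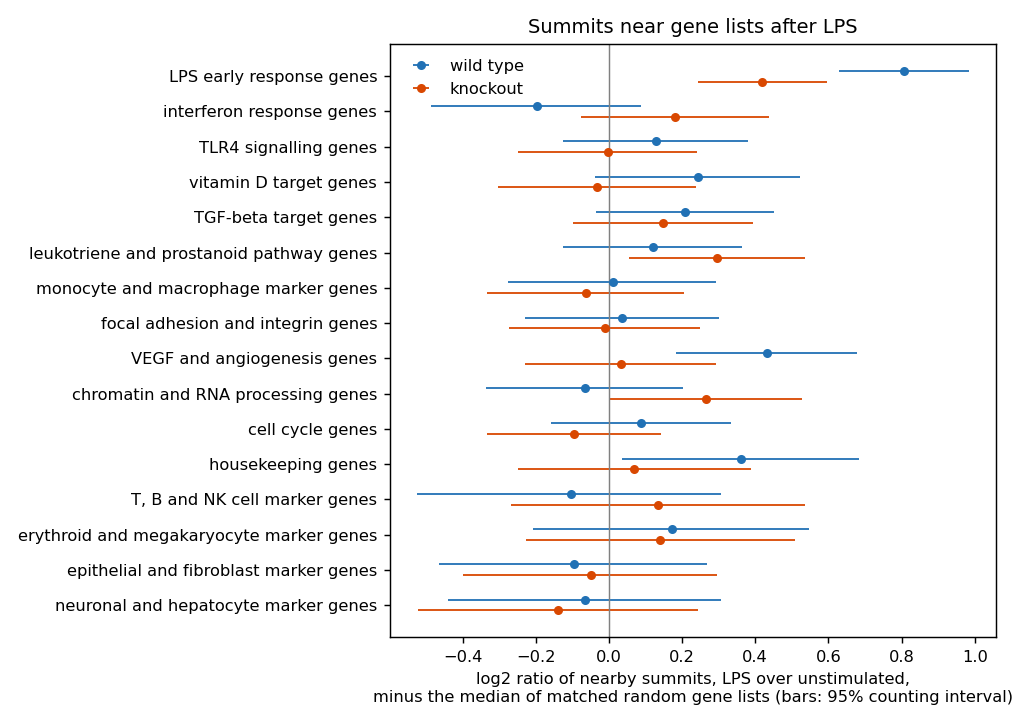
Log2 ratio of summits within 50000 bases of the members of each gene list, LPS over unstimulated, centred on matched random lists (x axis), in WT and KO cells; bars are 95% counting intervals. The LPS early response genes had the highest value in both genotypes, at 0.81 in WT and 0.42 in KO. In WT their interval overlapped those of VEGF and angiogenesis genes (0.43) and housekeeping genes (0.36). In KO it overlapped those of leukotriene and prostanoid pathway genes (0.29) and chromatin and RNA processing genes (0.27), among others.

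Summits lay at gene ends more often in the LPS lists. Within 1000 bases of an end were 6.69% of WT unstimulated summits (6.58 to 6.81), 8.57% of WT LPS (8.40 to 8.75), 7.23% of KO unstimulated (7.09 to 7.36) and 8.56% of KO LPS (8.40 to 8.71), against 4.39% of positions placed evenly for WT unstimulated. With equal numbers the shares were 8.19%, 8.57%, 8.09% and 9.33%. Among the top 5000 summits they were 15.2%, 19.0%, 14.3% and 21.1%. Of the regions in both LPS lists only, 9.19% (8.40 to 10.0) lay at gene ends, and of those in both unstimulated lists only 4.48% (4.18 to 4.79). Summit density varied widely between chromosomes. In WT unstimulated it was 169 per Mb on chromosome 13 and 87.0 on chromosome 4, against 33.8 on chromosome 19, 16.7 on 16 and 10.9 on 22. The cause was not tested, nor whether all summits mark open chromatin.

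**Figure D5:**
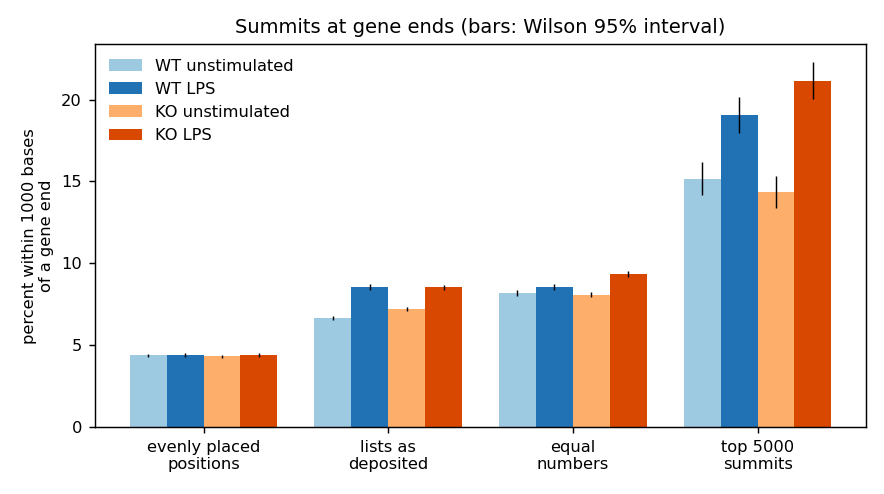
Percentage of summits within 1000 bases of a gene end (y axis) for evenly placed positions, the lists as deposited, equal numbers and the top 5000 summits; bars are Wilson 95% intervals. Among the top 5000, the LPS lists reach 19.0% and 21.1% and the unstimulated lists 15.2% and 14.3%.

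Across the 4 lists, a gene-end summit was present on average at 74.2% of housekeeping genes, 66.3% of LPS early response genes, 62.5% of interferon response genes, 61.7% of cell cycle genes and 59.8% of TLR4 signalling genes, against 32.6% of all protein-coding genes. Vitamin D targets reached 50.0%, TGF-β targets 49.0%, chromatin and RNA processing genes 47.3% and monocyte and macrophage markers 45.3%. Focal adhesion genes (36.2%), leukotriene and prostanoid pathway genes (31.8%) and VEGF and angiogenesis genes (29.5%) lay near the genome-wide level. Markers of other cell types were lower: 15.6% for erythroid and megakaryocyte, 12.5% for neuronal and hepatocyte, 10.6% for T, B and NK cell and 4.81% for epithelial and fibroblast markers. In all 4 lists, TLR4 itself, CXCL8, IL1B, DUSP10, a vitamin D target, and ZEB2, in a bin with fewer KO summits (log2 −0.86 and −0.95), carried a gene-end summit.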

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

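The tests of list length, gene density and shared neighbours below were set out before their values were seen, but on a pattern already noticed; random lists matched on gene density and single counting of summits were added after the data were examined.

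The number of summits differed between KO and WT in opposite directions in the 2 stimulation states, by −41752 without LPS and by 25628 after LPS. The difference was not tested, since each group has 1 list, and read depth is unknown.

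With the lists as deposited, the effect of LPS on nearby summits differed most between the 2 genotypes for 4 gene lists. In each of them the KO and WT values or the unstimulated and LPS values lay on opposite sides of the random median. Such a change of side was not peculiar to these 4. It was also seen for vitamin D targets and cell cycle genes in the LPS effect, and for housekeeping genes in KO against WT, among others. As KO minus WT on the centred log2 scale, the difference was −0.38 for LPS early response genes, 0.38 for interferon response genes, −0.40 for VEGF and angiogenesis genes and 0.33 for chromatin and RNA processing genes. With equal numbers of summits they were −0.23, 0.56, −0.19 and 0.26. In that setting leukotriene and prostanoid pathway genes (0.28) and neuronal and hepatocyte markers (−0.29) differed more than all of these but the interferon response genes. None of the differences was tested. The percentiles of the 4 gene lists as deposited among random lists, 0, 99.5, 0.54 and 98.9, describe these 4 summit lists only.

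The excess of summits near LPS early response genes after LPS was seen in both genotypes, at 0.81 and 0.42. List length as the whole cause is argued against by the lower of both values with equal numbers, 0.49. A general shift of the LPS lists toward gene-dense regions left 0.38 among random lists matched on gene density, and counting each summit once, for clusters such as the CXCL and CCL genes, left 0.41. The value of 0.41 was centred on random lists in which summits could be counted more than once. It has no percentile, so it cannot show how clustering of members affects the place among random lists. Stimulation, the factor in the design, stays open as a biological explanation and was not tested separately. GC content stays open as well, since no genome sequence was used here.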

How the results depend on the processing

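No paired analysis was possible because each group has 1 summit list, which leaves no replicates to pair. The motif alternatives were not run, since no genome sequence was used here. Chosen after the data were examined were the settings without altered segments, matched on chromosome or gene density, and with each summit counted once. Read depth is unknown, so list lengths and gene counts carry an unknown depth effect. The ratio of genotype to crossed regions was 1.25, and 1.16 to 1.37 over 4 alternatives; that of stimulation was 1.21, and 1.21 to 1.78, the highest at a score of at least 5. The 9 gene-list ratios outside the middle 95% of random lists kept their direction in all 6 alternatives run. Inside the middle 95% came, with equal numbers, LPS early response genes for KO against WT unstimulated (0.14, percentile 94.3), VEGF genes for KO against WT after LPS (−0.26, 3.67) and housekeeping genes for LPS in WT (0.18, 90.8), and, with a window of 10000 bases, interferon response genes for KO against WT after LPS (0.35, 96.5) and VEGF genes in that comparison (−0.24, 14.0) and for LPS in WT (0.35, 94.4). Outside the middle 95% came, with equal numbers, interferon response genes for LPS in WT (−0.27, 1.83) and in KO (0.29, 99.5) and monocyte markers for LPS in WT (−0.28, 1.16); with a window of 10000 bases, vitamin D targets for KO against WT unstimulated (0.38, 98.9) and for LPS in WT (0.37, 97.6) and chromatin genes for KO against WT unstimulated (−0.42, 0.61); matched on chromosome, vitamin D (0.26, 98.8) and TGF-β targets (0.25, 97.9) for LPS in WT; and without altered segments, interferon response genes for LPS in KO (0.27, 98.8). VEGF genes for LPS in WT had 0.28 with equal numbers. Single counting of summits gave no percentile. Chromatin and RNA processing genes for LPS in KO moved to 0.60 with a window of 10000 bases. Chromosome share ratios near 1 changed side with equal numbers in 1 stimulation state each for chromosomes 4, 8, 16 and 17. The cause of these moves and of those below was not tested, except that a higher score, the better-ranked 50% and equal numbers leave fewer summits by construction.

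A score of at least 5 left 37782, 17600, 31483 and 24391 summits in WT unstimulated, WT LPS, KO unstimulated and KO LPS. For the comparisons below values are given in the order KO and WT unstimulated, KO and WT LPS, WT LPS and unstimulated, KO LPS and unstimulated, each pair naming the list whose summits are counted. One-sided summits were then 13400, 19511, 14198, 7457, 5836, 25910, 10502 and 17682. In the better-ranked 50% of each list they were 20737, 37579, 29502, 18677, 13457, 47853, 22289 and 28949. With equal numbers the counts that moved were 52317 and 55695, for WT unstimulated against KO and against WT LPS.

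Shared percentages were 45.9, 35.5, 31.9, 39.9, 49.0, 27.2, 41.3 and 37.0 with reciprocal overlap, 70.9, 59.2, 53.9, 63.5, 73.7, 48.1, 65.2 and 59.4 in the better-ranked 50%, 48.4, 41.8, 57.6, 66.8, 31.4, 56.9 and 43.8 at a score of at least 5 (without KO unstimulated against WT, which did not move) and 48.7, 48.9, 44.1, 45.1, 47.2, 45.6 and 47.2 with equal numbers (without the last, which did not move).

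Regions at a score of at least 5 were 1441, 2086, 5059, 998, 1998 and 801 for WT only, KO only, unstimulated only, LPS only, WT unstimulated with KO LPS, and WT LPS with KO unstimulated. With equal numbers, 8475 and 6048 were in the unstimulated-only pattern and in WT unstimulated with KO LPS, and LPS-only regions went from 4756 to 7030. Gene-end counts that moved were, at a score of at least 5, 536, 140 and 135 for WT LPS against KO LPS, WT only and LPS only, and, with equal numbers, 1394, 1401, 179 and 344 for WT LPS only, WT unstimulated only, unstimulated-only in both genotypes and LPS-only in both, so that LPS-only genes came to outnumber unstimulated-only ones. The share of summits at gene ends was 8.19, 8.09 and 9.33% with equal numbers for WT unstimulated, KO unstimulated and KO LPS, and 12.2, 14.7, 12.8 and 14.4% with 2500 bases for WT unstimulated, WT LPS, KO unstimulated and KO LPS. The correlation of bins between states was 0.869 with equal numbers.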

Other observations

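The bin limit of 0.5, the 200-kb tiles, the stretches without KO summits and every test on chromosome segments were chosen after the data were examined; the bound for genotype patterns outside those segments was set before its value was seen.

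Without reference to the gene lists, 13331 tiles of 200 kb were ranked by the smaller of the LPS to unstimulated log2 ratios in WT and KO, scaled to list length with a prior of 3 summits. Both ratios were above 0.7 in 40 tiles and below −0.7 in 78, and in 59 they went beyond 0.7 in opposite directions; over tiles, which are not independent replicates, the correlation between genotypes was 0.13. The first tile, at 188400001 to 188600000 of chromosome 3, lies in LPP and went from 25 to 41 summits in WT and from 19 to 46 in KO. Others among the first 20 hold CD44, an adhesion receptor (13 to 21 and 14 to 28), the chemokine genes CCL3 and CCL4 (14 to 22 and 13 to 25), TNIP1, a regulator of NF-κB signalling (7 to 14 and 11 to 20), NAMPT (13 to 15 and 16 to 29), IDO2 (19 to 27 and 6 to 14) and EBI3, a cytokine subunit (2 to 5 and 3 to 7). These genes were named after their values were seen.

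The KO and WT lists differed over large segments. Of 552 bins of 5 Mb, 76 had a log2 ratio beyond 0.5 in the same direction in both states, 21 higher and 55 lower in KO. Length of the lists is argued against by chromosome 2, whose higher ratio with equal numbers was 0.711, and noise of single lists by the correlation of 0.893 over bins between the stimulation states, which share no list; for the LPS effect between genotypes it was 0.402. Neighbouring bins correlated at 0.800 for KO against WT and at 0.303 for LPS, as a copy number or clonal difference between the lines would give, and this remains a candidate explanation. Loss of 5-lipoxygenase acting on chromatin cannot be told apart from it, since the labels name 1 line per genotype.

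Stretches with at least 20 summits of WT and none of KO numbered 62 with their midpoint inside those 76 bins and 5 with it outside, and the converse 6 and 1. Of the 5, the stretch of chromosome 19 with the formyl peptide receptor genes held the most WT summits, 59. Whether it is deleted in the KO line was not tested.

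Genotype-only regions outnumbered the crossed ones 1.25 times, with an SD of 0.0203 over 1000 resamples of bins, and outside the 76 bins it was 1.16 with an SD of 0.0152, while 2132 WT-only and 1221 KO-only regions lay inside. The bound set beforehand was not passed by more than this spread, so that a part played by altered segments cannot be told apart from local differences between the genotypes. Outside the bins the stimulation patterns stood at 1.21.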
